A study of Arabidopsis thaliana with 2 samples.

How the data were processed

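Gene expression was compared between the Arabidopsis thaliana mutant cer6-2, which is deficient in surface wax, and its wild type, the accession Ler-0. Per the labels, RNA came from the aerial parts (leaves and stems) of plants grown at 22 °C and 80% relative humidity with 16 h of light and 8 h of dark, and 20 plants were pooled for each genotype. The sample labels give the age as 15 days and the design text as 2 weeks. Per the labels' protocols, total RNA was purified with an RNeasy plant kit, labelled with an Agilent direct labelling kit and hybridised to Agilent Arabidopsis 2 two-colour oligonucleotide arrays. Array 1 carried cer6-2 RNA in Cy3 and Ler-0 RNA in Cy5. Array 2 carried the same pair of genotypes with the dyes exchanged. Both arrays were taken as hybridisations of 1 RNA pool per genotype, so they count as 1 biological replicate, and no p-value is given.

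The authors deposited 1 value per feature and array, 22575 features in all, which was read as the log10 ratio of the channels. The log base is not stated in the sources used here. It was inferred from the limits of the values, which stop at 2 in size, a 100-fold ratio in log10, and from Agilent's usual output. The median was 0 in each deposited column, and 1475 features of array 1 and 1600 of array 2 stood at exactly 0, 1236 of them in both. Background correction, dye normalisation, image extraction software, filters and signal levels are not given in the sources used here. The values therefore could not be filtered on signal over background, and a ratio near 0 can belong to a transcript near the detection limit. The number of arrays limits the precision.

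The direction of the ratios is likely but not settled. The sources state the dyes but not which channel is the numerator. The ratio was read as Cy5 over Cy3, the Agilent convention, and array 1 was multiplied by -1, so that both arrays give cer6-2 over Ler-0. Of the named genes at least 2-fold from 0 in both deposited columns, 122 had opposite signs in them and 15 the same sign, so the columns were taken as not turned before deposit. No source states this, and if they had been turned, the counts of same-way and opposite genes would change places. Over all features these counts were 285 and 298, and 276 of the 298 were features without a matched gene that lay below 0 in both columns. Under the opposite reading every "higher" becomes "lower", and sizes and counts stay as they are. The series title names a low level of PR1 mRNA in cer6-2, but no feature is named PR1 here, so the title could not settle the direction. The title also names the mutant cer2, which was not analysed here.

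Values were converted to log2. Features were named through the platform annotation and a gene table of assembly TAIR10.1, by gene identifier, and no coordinate is given. Of the 22575 features, 9375 were annotated, 40 of them with several genes, and 13200 were unnamed. Of those with 1 gene, 9317 matched the gene table and 18 did not. They covered 9236 genes, 78 of which had several features that were averaged. Each gene's value is the mean of both arrays ± the SD between them. That SD covers labelling and hybridisation error and leaves out the variation between plants. A gene was called higher or lower when it was at least 2-fold apart the same way in both arrays. This is a rule of size, not a test.

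The rule for named genes was set before the data were examined. It takes the 12 genes with the largest mean higher in cer6-2 and the 12 with the largest mean lower among the called genes, CER6 and PR1 in any case, and the highest 2 and lowest 2 measured members of each gene list. The 18 gene lists with 293 genes were also set before the data were examined. They covered the mutated gene, wax synthesis and export, the other ketoacyl-CoA synthases, cutin synthesis, lipid transfer proteins, salicylic acid and PR defence, jasmonate and ethylene defence, the response to drought, abscisic acid and cold, rapid touch and wound response, heat shock proteins, light harvesting and carbon fixation, the circadian clock, flavonoid synthesis, glucosinolates, epidermis, trichome and stomata markers, flower markers, root markers and reference genes. The annotation named 36 of the 293 genes. A gene is called measured here if a feature was named for it, so a gene without one may still lie among the unnamed features. A median is given for lists with at least 3 measured members, a minimum set after the coverage of the lists was known. Each median was placed among the medians of 10000 random gene lists of the same size. The random lists could not be matched on expression level, because the table holds ratios alone. Another 9 lists were written after the values had been seen, and they appear in the closing section.

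The alternatives were centring each array on the median of its named genes, leaving out probes that differed over 2-fold between arrays, the median of a gene's probes, thresholds of 1.5-fold and 3-fold, the mean of both arrays as the criterion, each array alone, counting named probes or all features, reading the table as log2, and means in place of list medians. Leaving out features at exactly 0, leaving out a list's most distant member and reading the columns as turned before deposit were added after the data had been seen. The counting rule was tested on simulated data for 9236 genes with the observed spread between arrays. It called 98 of 100 genes set to 4-fold, 64 of 100 set to 2.5-fold, none of them the wrong way, and 19 of 9036 genes set to no change. The simulated error, including a part shared by both arrays, was drawn from that spread. No variation between plants or pools was simulated, so these counts cover technical error only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.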

Results

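RNA from the aerial parts of cer6-2 and Ler-0 plants was compared on 2 two-colour arrays with exchanged dyes. CER6 encodes a ketoacyl-CoA synthase that elongates very-long-chain fatty acids for surface wax. Each genotype was represented by 1 pool of 20 plants. Each value is the mean log2 ratio of cer6-2 over Ler-0 ± the SD between the 2 arrays (n = 2 technical measurements), and the difference between genotypes has no replicate check. The direction is likely, resting on the stated dyes and the Cy5 over Cy3 convention of the scanner's maker. With the opposite convention higher and lower exchange places. Both arrays were also taken as deposited without a change of sign, which no source states.

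The genes of the cold-regulated chloroplast proteins COR15B and COR15A were among those with the lowest ratios in cer6-2. They stood at -3.26 ± 0.15 and -2.54 ± 0.08, which are 9.57-fold and 5.82-fold lower. AT3G13610, the feruloyl-CoA hydroxylase needed for synthesis of the coumarin scopoletin, had the lowest mean of all named genes, -3.65 ± 1.31. JRG21 and AT2G38240, which encode oxygenases that hydroxylate jasmonic acid, stood at 3.57 ± 0.63 and 2.64 ± 1.1 and were among the highest genes. Of 9236 measured genes, 122 (1.32%) were at least 2-fold apart the same way in both arrays, 55 higher and 67 lower in cer6-2.

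The mutated gene and the gene of the series title come first in the rule for named genes. No feature was named CER6 or PR1 here, so neither gene has a value, and the mutated gene could not check the labels.

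Among the other genes of the 12 largest lower, the class III peroxidases Prx37 and AT4G36430 stood at -2.69 ± 0.30 and -1.997 ± 0.336. OSM34, an osmotin-like protein of the thaumatin family, stood at -2.25 ± 0.22, and the plant defensin PDF1.2, a marker of jasmonate and ethylene signalling, at -2.09 ± 0.92. AT1G26390, an oxidase of the berberine bridge enzyme family, stood at -2.24 ± 0.15, and AT2G15220, a basic secretory protein, at -2.74 ± 0.61. The others were AT4G30650, of a family of small membrane proteins induced by low temperature and salt (-2.45 ± 0.92), AT1G51090 (-2.37 ± 0.02) and the glutaredoxin AT2G47880 (-2.28 ± 0.67).

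The 12 largest higher genes were of mixed function. AT4G25580, of the CAP160 family, stood at 3.30 ± 0.23, and AT1G60740, a type II peroxiredoxin with close paralogs, at 3.19 ± 0.03. The linker histone HIS1-3, known to be induced by drought, stood at 2.43 ± 0.0027, a 5.40-fold difference. A pair of genes act in amino acid breakdown. These were MGL, methionine gamma-lyase, at 2.16 ± 0.21 and AT1G21400, a subunit of the branched-chain keto acid dehydrogenase, at 1.99 ± 0.03. The glutaredoxin AT3G62950 stood at 2.07 ± 0.01, and the methyltransferase gene NAMT1 at 1.98 ± 1.103. AT1G62510, AT2G32150 and AT4G36850 stood at 2.14 ± 0.98, 2.08 ± 0.99 and 1.90 ± 0.09.

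**Figure D1:**
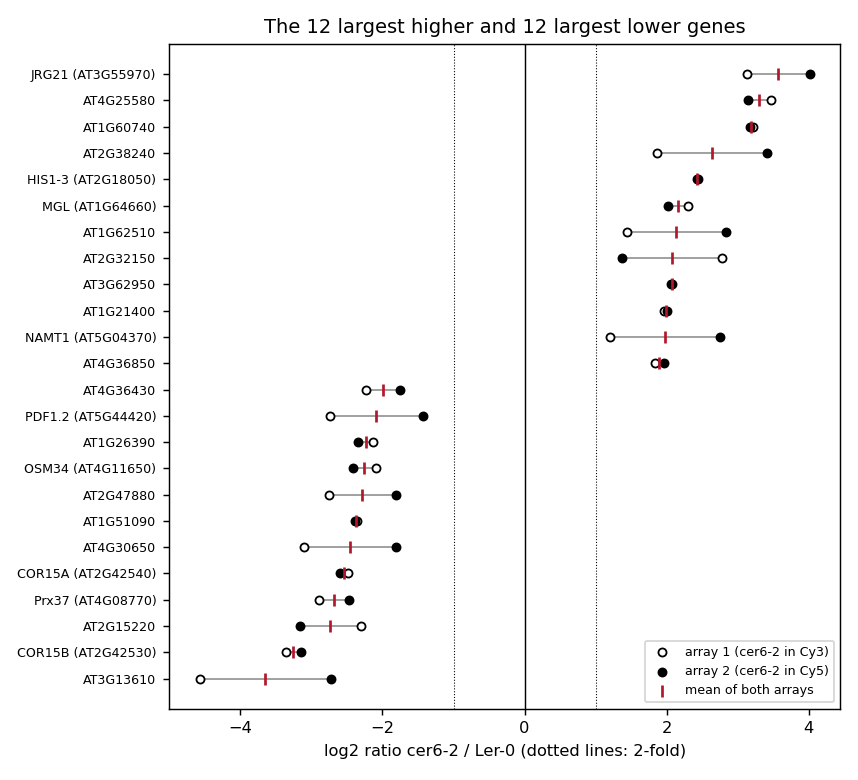
Log2 ratio of cer6-2 over Ler-0 (likely direction) for the 12 largest higher and the 12 largest lower genes, with open circles for array 1, filled circles for array 2 and red bars for their mean. HIS1-3 has nearly equal values in both arrays (2.44 and 2.43), whereas AT3G13610 lies at -4.57 in array 1 and -2.73 in array 2.

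Of 5 measured members of the drought, abscisic acid and cold list, 2 were called lower (COR15B and COR15A) and none higher. The median was -1.20, below those of all 10000 random lists of this size, a rank that treats the members as independent. KIN2, a small protein induced by cold and abscisic acid, stood at -1.20 ± 0.42, and its adjacent paralog KIN1 at -0.22 ± 0.41, with opposite signs in the 2 arrays. The dehydrin COR47 had a mean of 0.08 ± 1.11, with 0.87 in array 1 and -0.70 in array 2. COR15A and COR15B are adjacent paralogs whose probes can share signal, so they are not independent, and without COR15B the median was -0.71, at percentile 0.040 of random lists, a setting chosen after the data had been seen. Called genes outside this list, with names or families linked to cold or drought, went both ways. HIS1-3, known to be induced by drought, stood at 2.43 and AT4G25580, of the CAP160 family, at 3.30. AT4G30650, of the family induced by low temperature and salt, stood at -2.45 and COR27 at -1.50.

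The lists of defence genes were thinly covered. In the salicylic acid and PR defence list, 1 of 2 measured members was called lower, the transcription factor WRKY53 at -1.27 ± 0.21. The glutaredoxin GRX480 stood at -0.30 ± 0.14. In the jasmonate and ethylene defence list, PDF1.2 was called lower and the thionin THI2.1 was not called, at -0.07 ± 0.39 with opposite signs in the 2 arrays.

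The wax list addresses the pathway that the mutation affects. Only 3 of its 22 genes were measured, so most of the list has no value here, and none of the 3 was called. CER26L (AT3G23840) and CER26 (AT4G13840), which are acyltransferase-like proteins related to the wax elongation factor CER2, stood at -0.50 ± 0.85 and -0.32 ± 0.55. The wax ester synthase WSD1 stood at -0.13 ± 0.14. The median was -0.32, lower than in all but 2.97% of random lists, yet it was 0.07 in array 1 and -0.71 in array 2, so its sign differed between the arrays. The lists of other ketoacyl-CoA synthases, cutin synthesis, lipid transfer proteins and flower markers had no member with a named feature. Whether unnamed features cover those genes is unknown.

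The remaining lists held no called gene. The 4 heat shock proteins measured had means below 0, but HSP22 and HSP17.6C had opposite signs in the 2 arrays. The means ran from HSP17.8 at -0.67 ± 0.43 and HSP22 at -0.27 ± 1.37 to HSP15.7 at -0.13 ± 0.16 and HSP17.6C at -0.08 ± 0.41. Their median was -0.20, at percentile 6.38 of random lists. The 3 genes of light harvesting and carbon fixation had a median of 0.08, at percentile 72.0. Among them were Rubisco activase, RCA, at 0.08 ± 0.04 and the antenna proteins LHCB4.1 and LHCB4.2 at 0.08 ± 0.07 and 0.25 ± 0.66. The 6 reference genes had a median of 0.02, at percentile 58.7, and the 2 arrays gave opposite signs for each of them. Their extremes were the elongation factor gene EF1A at -0.15 ± 0.25 and GAPC2 at -0.04 ± 0.65, against UBC21 at 0.05 ± 0.48 and SAND at 0.07 ± 0.32. The 3 root markers went both ways, with EXPA7 at -0.46 ± 1.02, EXPA18 at -0.15 ± 0.30 and the beta-glucosidase PYK10 at 0.73 ± 0.08.

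Lists with 1 or 2 measured members covered other processes, and none of these was called. The touch and wound genes ZAT10 and CML38 stood at 0.06 ± 0.40 and 0.28 ± 0.11, and the clock gene GI at -0.34 ± 0.07. The anthocyanin genes DFR and UF3GT stood at -0.46 ± 0.18 and -0.11 ± 0.63. The glucosinolate genes BCAT4 and UGT74B1 stood at 0.75 ± 0.37 and 0.20 ± 0.82, and MUTE, a regulator of stomatal development, at -0.33 ± 0.10.

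**Figure D2:**
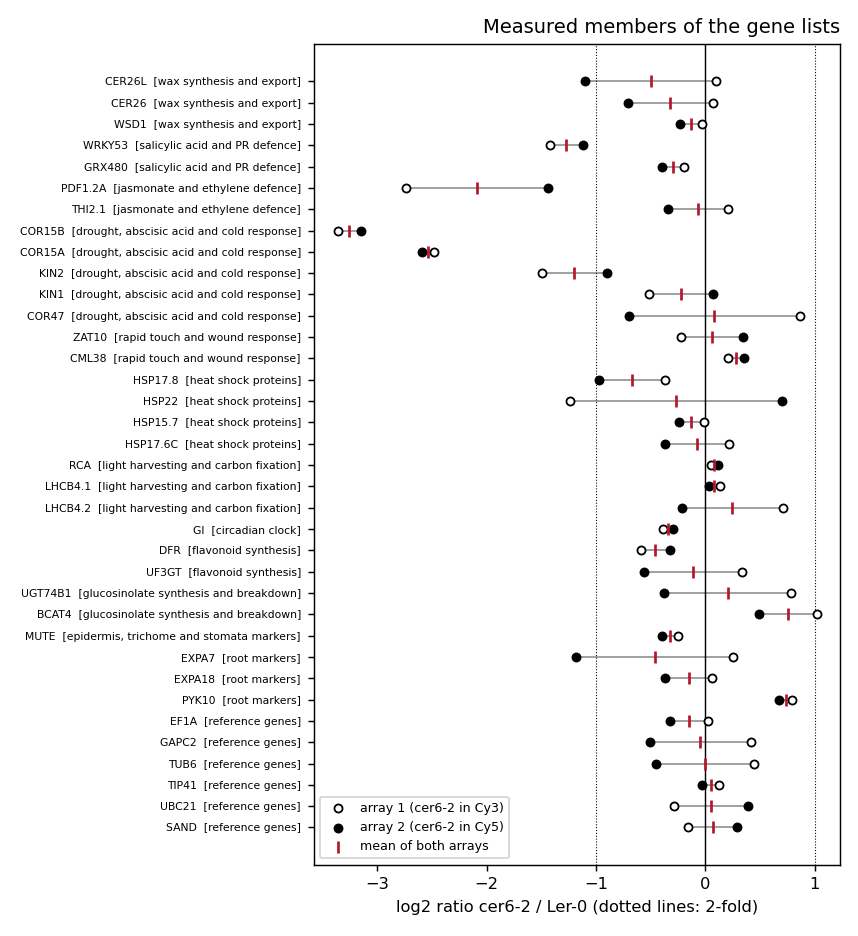
Log2 ratio of cer6-2 over Ler-0 (likely direction) for the 36 measured members of the gene lists, with open circles for array 1, filled circles for array 2 and red bars for their mean. COR15B and COR15A lie below -2 in both arrays, and the reference genes lie on either side of 0.

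The spread between the arrays shows technical error alone, without the variation between plants or pools. The distance of an array from the mean of both had an SD of 0.29 over genes, which is 1.23-fold. The correlation between the arrays across genes, which are not independent replicates, was r = 0.17 (Spearman's rho -0.04) over all 9236 genes. Over the 2215 genes at least 1.5-fold apart in either array it was r = 0.30 (rho 0.20). Over the 13258 features without a matched gene, which enter no comparison between genes, it was r = -0.70 (rho -0.15). These features include 248 at least 10-fold to the side of the same dye in both arrays. The correlation without those 248 was not computed, so r = -0.70 may not describe the other unmatched features. Against the 122 genes at least 2-fold apart the same way stood 15 that were 2-fold apart in opposite ways, 13 of them below 0 in both deposited columns. Those 13 were brighter in Cy3 under the direction read here, and would be brighter in Cy5 under the opposite one. At 3-fold the counts were 31 and 0.

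**Figure D3:**
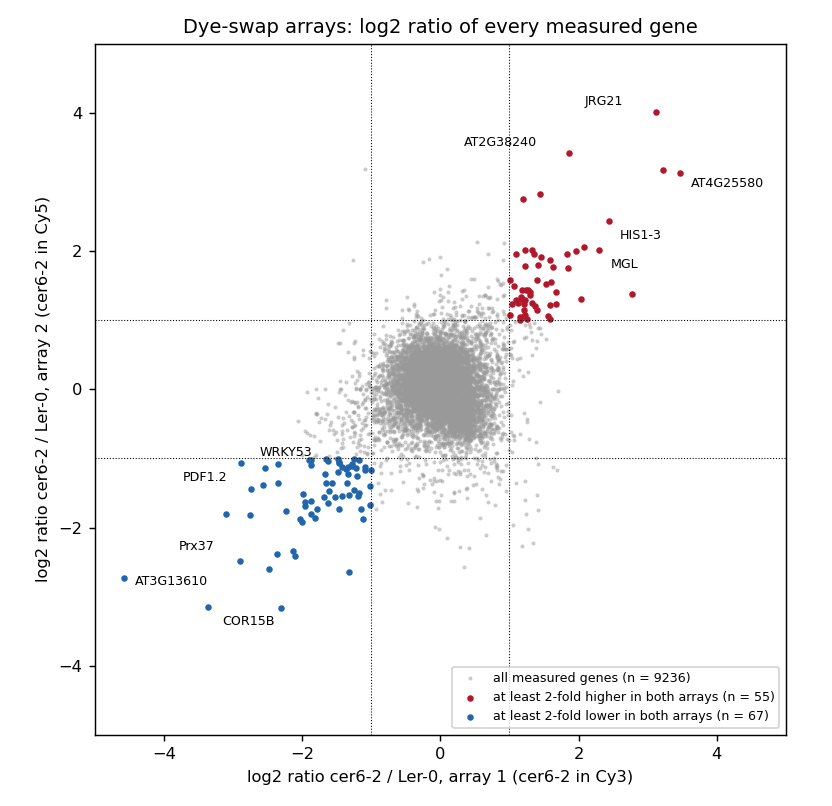
Log2 ratio of cer6-2 over Ler-0 (likely direction) in array 1 on the x axis and in array 2 on the y axis, for 9236 genes, with dotted lines at 2-fold. The 55 higher and 67 lower genes lie in the upper right and lower left corners, and most other genes form a cloud around 0 with little correlation.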

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

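The counts and features here were chosen after the values had been seen. The 13258 features without a matched gene (13200 unnamed, 40 with several genes and 18 outside the gene table) entered no comparison between genes, and 161 of them were at least 2-fold apart the same way in both arrays, 69 higher and 92 lower in cer6-2 under the direction used in the report. A larger number, 283, were at least 2-fold apart in opposite ways. The difference between genotypes has no replicate check for these features either. Feature 14757 stood at the limit of the table in both arrays, at -6.64 on the log2 scale, so the 100-fold lower ratio in cer6-2 is a bound. The next lowest such feature, 3978, stood at -4.27 ± 0.40, and the highest, 12415, at 3.65 ± 0.47.

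Among the 283 opposite features were 248 at least 10-fold to the side of the same dye in both arrays, whichever genotype carried it. All 248 lay below 0 in both deposited columns, and 0 lay above. That side is Cy3 under the direction read here and Cy5 under the opposite one. No gene name belongs to any of the 248. These features were in none of the gene counts.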

How the results depend on the processing

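Counts of called genes depended on the threshold more than on centring or averaging. The main counts were 122 genes, 55 higher, 67 lower and 15 opposite ways. At 1.5-fold they were 342, 166, 176 and 135, and at 3-fold 31, 11, 20 and 0. By the mean of both arrays they were 212, 91 and 121. With each array alone they ran from 329 to 369 in all, 114 to 169 higher and 200 to 215 lower. Over all features they were 285, 125, 160 and 298. With the columns read as turned before deposit, a setting added after the data had been seen, they were 15, 2, 13 and 122. Read as log2, the table gave 0, 0, 0 and 0. Without probes differing over 2-fold between arrays the opposite count was 0, by construction, and all 110 genes called were among the 122. Centring kept 119 of the 122. The drought, abscisic acid and cold median was -1.87 without those probes and -0.71 without its most distant member, a setting added after the data had been seen. The heat shock value was -0.29 as a mean, and -0.31 to -0.19 by array. The root marker median was 0.29 without the differing probes, against -0.15, so its direction changed. That setting drops EXPA7 and leaves only EXPA18 and PYK10, fewer than the minimum of 3 members. With all its members the root marker median was 0.258 in array 1 and -0.365 in array 2. The reference gene median ran from -0.177 to 0.075 by array. The correlation between arrays was 0.30 over genes at least 1.5-fold apart in either array. The cause was not tested for these, except where construction sets it. Of 57 named genes, 19 had opposite signs in the 2 arrays, so either array alone decides their direction. None of the 19 was called, as the calling rule requires. Centring shifted the named genes by -0.012 and changed the sign of 0 of them. Reading the table as linear ratios was not run, because values lie below 0. No paired analysis was possible because both arrays compare the same pair of pools. Signal over background is not in the values used here, so its limit on low transcripts is unknown.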

Other observations

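The gene families and tests in this part were all chosen after the values had been seen, several of them because a member stood among the extremes, so their counts describe these arrays and are not independent evidence. Chitinases, enzymes that degrade fungal cell walls, had lower ratios in cer6-2, with 6 of 11 measured members called lower, none higher, and a median of -1.33. AT2G43590 stood at -1.98 ± 0.93, AT1G02360 at -1.83 ± 0.19 and CHI (AT2G43570) at -1.79 ± 0.24. CHI and AT2G43590 are neighbouring family members whose probes can share signal. Of 52 class III peroxidases, 7 were called lower and none higher, and 40 were below 0 with a median of -0.21. That median was -0.096 in array 1 and -0.508 in array 2, and the arrays disagreed in sign for 18 of the 52. The berberine bridge enzyme family went both ways, with 2 of 22 higher (AT1G30730 at 1.80 ± 0.07, AT1G30720 at 1.34 ± 0.15) and 2 lower (AT1G26390 and AT1G26380 at -1.54 ± 0.02), and a median of -0.02.

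Genes of amino acid breakdown had higher ratios in cer6-2, with 7 of 16 measured members called higher, none lower, and a median of 0.92. Beside MGL and AT1G21400 these were AT5G38710, a proline dehydrogenase, at 1.61 ± 0.28, AT4G33150, which acts in lysine breakdown, at 1.54 ± 0.18, and the leucine pathway genes IVD and MCCB at 1.31 ± 0.18 and 1.299 ± 0.400, with ALDH7B4 at 1.15 ± 0.10. The lowest member, AT5G09300, stood at -0.74 ± 0.13. Of 4 jasmonate oxidases, JRG21 and AT2G38240 were called higher, AT5G05600 stood at 1.198 ± 0.524 and AT3G11180 was listed at 0 in both arrays. Genes of the ER body, a compartment that stores beta-glucosidases, had no called member among 11, but 9 were above 0 and the median was 0.76, with NAI1 at 0.88 ± 0.13, NAI2 at 0.79 ± 0.20 and BGLU21 at -0.75 ± 0.26.

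Dye bias of single probes was weighed for the genes at least 2-fold apart in array 1. With the columns read as not turned before deposit, such a bias cancels in the mean and would turn the sign in array 2 for most of them. After array 1 was turned, 258 of 329 genes (78.4%) kept their sign and 71 changed it, and of 369 genes chosen in array 2, 70.5% kept theirs. Under that reading the counts argue against dye bias as the whole cause. The reading itself rests on the same kind of count, and had the columns been turned, these genes would follow the dye, so dye bias stays open to that extent. The genotype and a difference between the pools stay open too, since 1 pool per genotype confounds them.

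For the 7 lower peroxidases, less root tissue in the cer6-2 pool is a candidate explanation, because many peroxidases are root-expressed. The labels give leaves and stems as the material, so this would need more roots carried over in the Ler-0 pool than in the cer6-2 pool. Their median was -1.84, but they were chosen as called lower, so a median well below 0 was set in advance. All 52 measured class III peroxidases had a median of -0.21, and 7 other root-expressed genes had one of -0.15 with an SD of 0.47. Only 2 of those 7 had the same sign in both arrays, and they went opposite ways (BGLU21 and PYK10 at 0.73 ± 0.08), XTH26 was listed at 0, and 3 belong to the ER body list as well. With no signal levels and so few usable genes, root tissue and genotype cannot be told apart for these peroxidases.

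For the amino acid breakdown genes, harvest at another time of day and a lower carbohydrate supply were weighed. Of 2 measured genes of a wider clock list, GI (-0.34 ± 0.07) and AT5G52660 (0.01 ± 0.03), 0% were at least 1.5-fold apart in both arrays. COR27, which that list leaves out, was called lower at -1.50 ± 0.21. These are too few genes to argue for or against a difference in time of day. The 3 measured genes known to respond to sugar starvation or darkness, ATL8, AKINBETA1 and AT3G15450, stood at 1.63 ± 0.56, 1.14 ± 0.32 and 0.93 ± 0.26, and their median lay at percentile 99.99 of random lists. That test is void as evidence, because these values had been seen to be higher when the list was written. Both explanations may still hold, and neither can be told apart from an effect of the mutation.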
